A study of Mus musculus with 2 samples.

How the data were processed

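Total RNA-seq was analysed from 2 libraries of mouse adrenal gland at postnatal day 0, 1 library per pup, each from 2 adrenals. Per the labels, total RNA was extracted with Ambion mirVana and a SMARTer ultra low input kit manual is listed among the protocols. Per the labels, the libraries started from 10 ng, the size range was above 200 (no unit given), and spike-ins were added. Grouping followed the labels: both libraries form 1 group, and the replicate number is the pup number. No sample was left without a group.

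For each library the authors deposited a gene table and a transcript table. Per the file headers these hold expected counts (estimated counts that need not be whole), and a posterior mean count with its standard deviation. The deposited TPM values are scaled to 1 fixed total over all rows of a file, spike-ins included, and the quantifier's interval for TPM is given beside them. The deposited FPKM values are scaled by effective transcript length and by the reads of the library. The transcript tables also carry the deposited isoform percent, the share of a gene's TPM in each transcript. The text file deposited with each library names the mm10 build and GENCODE annotation M4. The aligner, the quantifier and their versions are not given in the sources used here, though the column names are those RSEM writes. How reads of near-identical genes were divided is known only through the posterior standard deviations, and strand handling is not given in the sources used here.

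The gene tables had 69691 rows, of which 43346 were Ensembl genes, 97 spike-ins and 26248 rows with a number as name. The numbered rows held 2.65e-05% of counts in pup 1 and 9.59e-05% in pup 2, and the spike-in rows 0.0138% and 0.00251%. Both kinds were left out of library sizes and gene comparisons. Symbols, coordinates, gene types and GC content came from GENCODE M21 on the same build, matched by Ensembl identifier, and 42462 genes had a symbol. Depth was 41510071 estimated counts in pup 1 and 40800539 in pup 2. Counts were not whole for 15.3% and 15.9% of the Ensembl gene rows and were rounded.

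Levels are TPM per pup with the mean and SD (n = 2). Ratios are log2 of pup 2 over pup 1, from rounded counts plus 0.5 after TMM scaling in edgeR 4.0.16 (R 4.3.3), for genes with a mean count of at least 10. Printed folds of named genes use scaled counts without the added 0.5. The biological coefficient of variation came from the common dispersion of edgeR. Intervals of a ratio are exact binomial 95% intervals, and a fold against 0 counts is a lower bound against 3 counts in that library. Intervals and bounds cover counting error only, since reads without molecular identifiers are not independent molecules. Correlations used log2(TPM + 1) over genes with TPM of at least 1 in either pup. No test between the pups was run, because each pup is 1 library.

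Before the data were examined, 22 gene lists with 237 distinct symbols were fixed for cell types, pathways, neighbouring organs and RNA classes, and 1 symbol (Snhg1) had no match. They are described by level and by the percentile of their median log2 ratio among 10000 random lists matched on mean expression in 50 bins. The percentile describes these libraries only and is not a test, since genes of a list vary together. Tallies of direction count the sign of each ratio, however small. Cyp11b2 belongs to the steroidogenesis and the glomerulosa list. The rule for named genes was fixed at the same time. It takes the 10 nuclear genes with the highest mean TPM, the 4 highest of each list with up to 3 members under TPM 1 in both pups, and any member of the steroidogenesis and sex chromosome lists. It also takes the 5 genes with the largest ratio in each direction at a mean count of at least 100, and the isoforms of the 4 highest genes of the steroidogenesis, chromaffin and imprinted growth lists. Genes named outside the rule are said to be so, and some genes the rule takes are not reported here.

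The alternatives fixed beforehand were DESeq2 1.42.0 size factors or spike-in counts for scaling, other count and TPM minimums, another pseudocount, posterior mean counts, FPKM, summed transcript TPM, TPM over nuclear genes, and leaving out each pup. Chosen after seeing the data were the removal of a trend with length and GC content (polynomials of degree 3), genes whose posterior standard deviation is at most 10% of the mean, TMM-scaled CPM for list levels, and 5 further gene lists written before their values were looked at. Other steps used python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

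The scripts were tested on simulated data for the comparison of pup 2 over pup 1. A coefficient of variation of 20% was recovered as 21.6% over 18616 genes. Of 100 genes changed 4-fold, 100% were found over 2-fold apart, and of 100 changed 2-fold, 46%, against 1.80% of 13670 unchanged genes. The 46% follows from a cutoff at the size of the change. The simulated variation of 20% lies below the 33.4% of the data, so 1.80% is not a background rate for these pups. Of 200 random lists without change, 6.5% fell outside the central 95%, and a list of 10 genes shifted by 1 on the log2 scale fell at percentile 99.99.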

Results

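Total RNA was sequenced from the adrenal glands of newborn mice of strain B6NCrl, at postnatal day 0. The adrenal gland has an outer cortex that makes steroid hormones and an inner medulla of chromaffin cells that make catecholamines. There were 2 libraries, each from the 2 adrenals of 1 pup, and the labels give both pups the same number for the pregnant animal. Each library was made from 10 ng of RNA with added spike-in RNA, and the sex of the pups was not collected per the labels. The libraries held 41510071 estimated counts in pup 1 and 40800539 in pup 2. Both belong to 1 group, so the design implies an account of expression in the newborn gland and of how far the pups lie apart, with no contrast between conditions. With 1 library per pup, a difference between the pups has no replicate check and no p-value is given. Values are given as mean ± SD over the pups (n = 2) or per pup, and intervals cover counting error only.

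Several enzymes of steroid synthesis were abundant in both glands, and Hsd3b1 and Cyp21a1 were among the 12 nuclear protein-coding genes with the highest mean TPM. Hsd3b1, a dehydrogenase of steroid synthesis (ENSMUSG00000027871.12, chromosome 3, 98852194 to 98859794, minus strand, mm10), stood at 3733 ± 1788 TPM (SD, n = 2). Cyp21a1, an adrenal steroid hydroxylase (ENSMUSG00000024365.9, chromosome 17, 34801348 to 34804561), stood at 3259 ± 2445 TPM (SD, n = 2). Cyp11a1, whose enzyme cleaves the side chain of cholesterol (ENSMUSG00000032323.9, chromosome 9, 58006411 to 58027023), stood at 1870 ± 1370 TPM, and Cyp11b1, which completes corticosterone (ENSMUSG00000075604.5, chromosome 15, 74834125 to 74841643), at 1784 ± 1251 TPM. Of the 18 fixed genes of steroidogenesis, 17 reached TPM 1 in both pups, with a median of 124 TPM in pup 1 and 387 TPM in pup 2.

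The steroidogenic genes were all higher in pup 2. After TMM scaling of the counts, the median log2 ratio of pup 2 over pup 1 was 1.06 over 18 genes, at percentile 100 of 10000 random lists matched on expression. Star, which carries cholesterol into mitochondria, stood at 477 TPM in pup 1 and 1271 TPM in pup 2, with a log2 ratio of 1.03 by scaled counts. Across genes, ratios of TPM ran above ratios of scaled counts by a median of 0.39 on the log2 scale. The ACTH receptor gene Mc2r had 118 and 249 TPM, and Nr5a1, the transcription factor of steroidogenic cells, 39.9 and 143 TPM. The smallest ratio belonged to Cyp17a1, an enzyme of cortisol and androgen synthesis, with 19 and 22 counts (0.27 and 0.45 TPM) and a log2 ratio of 0.12 whose 95% interval ran from -0.83 to 1.09. A difference in Cyp17a1 was therefore not detectable at this depth. The aldosterone synthase gene Cyp11b2 stood at 18.6 ± 8.56 TPM (SD, n = 2), far below its neighbour and paralog Cyp11b1. Reads can be shared between these paralogs, but the quantifier's intervals for Cyp11b2 were narrow (11.4 to 13.3 TPM in pup 1 and 22.8 to 25.7 TPM in pup 2).

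Genes of the chromaffin cells were expressed in both pups and split in direction between them. Npy, a peptide co-released with catecholamines, stood at 833 TPM in pup 1 and 1386 TPM in pup 2. The granule protein genes Chga (557 and 1522 TPM) and Chgb (265 and 791 TPM) and the tyrosine hydroxylase gene Th (303 and 573 TPM) were the next highest of the list. All 22 fixed genes reached TPM 1 in both pups, with a median of 88.0 TPM in pup 1 and 69.9 TPM in pup 2. By scaled counts 13 were higher in pup 1 and 9 in pup 2, with a median log2 ratio of -0.30 at percentile 2.09 of the random lists. Named after their values were seen, Chgb (1.19), Scg2 (1.13), Pnmt (1.08) and Chga (1.06) had the highest log2 ratios, and Ret (-1.32) and Slc18a2 (-1.20) were among the lowest. The log2 ratio of the steroidogenic over the chromaffin median was 0.50 in pup 1 and 2.47 in pup 2, or 1.48 ± 1.39 (SD, n = 2). From summed TPM it was 1.42 and 1.90, a smaller gap between the pups, since the summed chromaffin TPM was higher in pup 2 (3410 and 6166) while the median was lower.

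Neuronal genes were higher in pup 1, in the opposite direction to the steroidogenic genes. Stmn2, a microtubule regulator of neurons, stood at 366 TPM in pup 1 and 113 TPM in pup 2. The growth cone gene Gap43 (292 and 97.9 TPM), the neuronal tubulin gene Tubb3 (221 and 71.1 TPM) and the peripherin gene Prph (178 and 49.1 TPM) went the same way. All 9 genes fixed for sympathetic neurons were higher in pup 1, with a median log2 ratio of -2.02 at percentile 0 of the random lists, a 4.05-fold difference. All 8 Schwann cell and glia genes were also higher in pup 1, with a median of -0.84 at percentile 0.17. Among these, Fabp7 had 125 and 54.2 TPM and Sox10 5.64 and 5.39 TPM. Scaling by the spike-in counts moves the median of all genes by 2.57 on the log2 scale and turns the sign of the chromaffin, neuron and glia medians (2.27, 0.55 and 1.73), so the directions given here and for all other lists are relative to the bulk of genes.

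**Figure D1:**
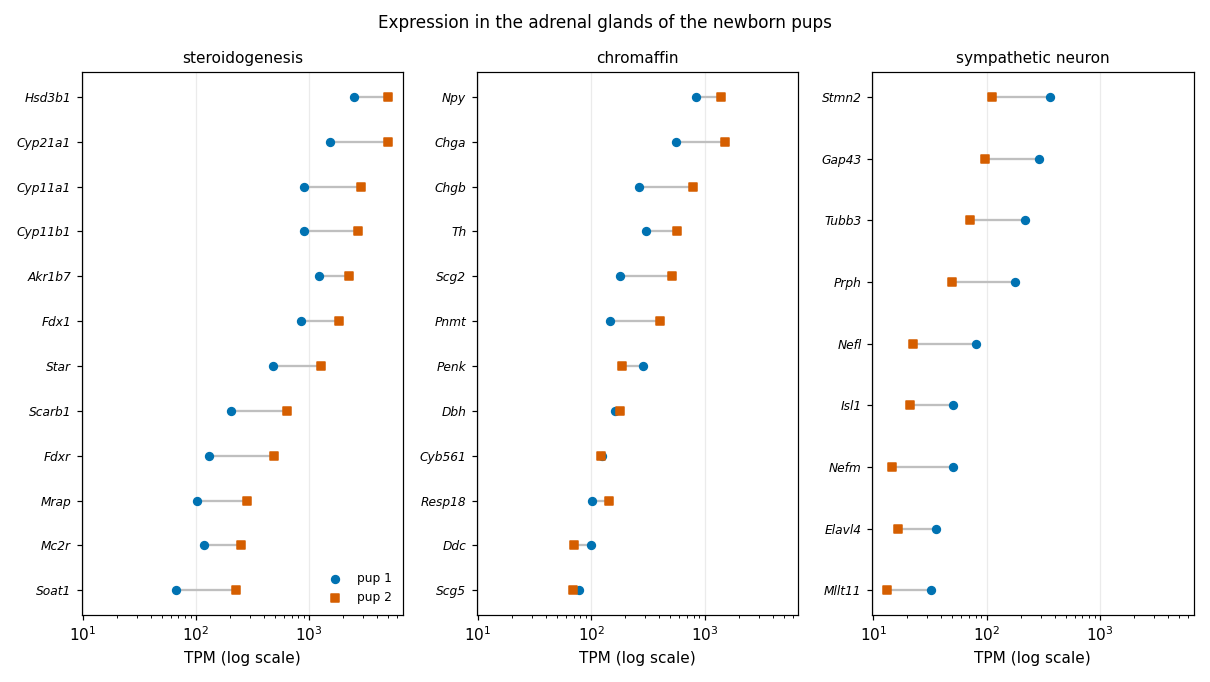
TPM of the up to 12 most abundant fixed genes for steroidogenesis, chromaffin cells and sympathetic neurons on a log axis, with a circle for pup 1, a square for pup 2 and a line joining them. All 12 steroidogenic genes shown lie further right in pup 2 and all 9 neuron genes in pup 1, while the chromaffin genes go both ways. Ratios of TPM, pup 2 over pup 1, ran above ratios of scaled counts by a median of 0.39 on the log2 scale.

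Genes of the outer cortex and of the transient inner zone were present at lower levels. The 12 fixed genes of the zona glomerulosa and capsule all reached TPM 1 in both pups and divided evenly, 6 higher in each pup, with a median log2 ratio of 0.18 at percentile 89.9. That median covers a wide split, with members from -1.55 (Rspo3) to 0.84. Of the 4 most abundant members, Rspo3, Tcf21 (-1.20) and Nr2f2 (-0.80) were higher in pup 1 and Dab2 (0.65) in pup 2. Named after their values were seen, Gli1 (-0.68), Agtr1b (-0.27) and Axin2 (-0.14) were also higher in pup 1. In pup 2, Shh (0.84), Vsnl1 (0.84), Wnt4 (0.80), Cyp11b2 (0.59) and Lef1 (0.51) were higher. Glomerulosa and capsule genes were not listed apart beforehand, so the even division describes neither part alone. Dab2 led this list with 76.0 TPM in pup 1 and 153 TPM in pup 2, followed by Tcf21 with 139 and 79.0 TPM, Nr2f2 with 61.7 and 45.9 TPM and the Wnt pathway activator gene Rspo3 with 66.6 and 29.6 TPM. Akr1c18, a marker of the X-zone of the mouse cortex, had 31.6 and 39.5 TPM, Thrb 1.45 and 3.02 TPM, and Pik3c2g was under 1 TPM in both (0.38 and 0.41). The median log2 ratio of these 3 genes was -0.07 at percentile 41.9. Among 17 genes of cholesterol synthesis, 13 were higher in pup 1 by scaled counts with a median of -0.31 at percentile 0.76, whereas the median TPM was higher in pup 2 (23.0 and 26.1). Fdps (104 and 141 TPM), Dhcr7 (64.0 and 141 TPM), Hmgcs1 (62.9 and 98.4 TPM) and Msmo1 (53.6 and 79.0 TPM), its 4 most abundant members, all had log2 ratios above 0.

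Imprinted growth genes were abundant. Cdkn1c, a growth-restraining cell cycle inhibitor, stood at 882 ± 417 TPM (SD, n = 2), Meg3 at 483 ± 182 TPM, Dlk1 at 475 ± 14.9 TPM and Mest at 413 ± 40.1 TPM. All 15 members reached TPM 1 in both pups, and 9 were higher in pup 1, with a median log2 ratio of -0.22 at percentile 21.8 and a median TPM of 111 and 116. The 10 proliferation genes divided evenly between the pups with a median of 0.02 at percentile 42.6. They included Cdk1 at 152 and 142 TPM, Birc5 at 54.1 and 65.6 TPM, Top2a at 30.0 and 36.1 TPM and Ccna2 at 24.5 and 35.0 TPM.

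Relative to the bulk of genes, vessel genes were higher in pup 2, whereas connective tissue, blood and liver genes were higher in pup 1 except under spike-in scaling, where they were higher in pup 2. Of 10 endothelial genes, 8 were higher in pup 2, with a median log2 ratio of 0.73 at percentile 100. Plvap, a protein of fenestrated capillaries, had 42.6 TPM in pup 1 and 97.9 TPM in pup 2, Emcn 41.7 and 63.0 TPM, and Esam 15.6 and 33.8 TPM, while Egfl7 (94.0 and 118 TPM) had a log2 ratio of -0.07. The 10 stroma genes had a median of -0.58 at percentile 0.91, and all were higher in pup 1 but Fbln1, whose counts were level (interval of the log2 ratio -0.07 to 0.07), led by the collagen genes Col3a1 (574 and 591 TPM) and Col1a1 (492 and 490 TPM), Dcn (472 and 378 TPM) and Postn (521 and 314 TPM). TPM ratios ran above count ratios by a median of 0.39 on the log2 scale, so genes and lists near 0 can differ in direction between the measures, as Col3a1 did. Of 12 leukocyte genes, 9 were higher in pup 1 with a median of -0.50 at percentile 0.13, and S100a8 (483 and 248 TPM), Lyz2 (225 and 138 TPM), S100a9 (228 and 123 TPM) and C1qb (173 and 148 TPM) were the most abundant.

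Liver genes were abundant in both adrenal libraries, with a median of 451 TPM in pup 1 and 333 TPM in pup 2. Whether their RNA came from liver tissue was not tested. Trf, the transferrin gene, had 705 TPM in pup 1 and 566 TPM in pup 2, the apolipoprotein gene Apoa1 607 and 450 TPM, Ahsg 534 and 435 TPM, and Apoa2 489 and 360 TPM. All 8 liver genes were higher in pup 1, with log2 ratios between -0.92 and -0.61 and a median of -0.81 at percentile 0.21. Of 9 erythroid genes with enough counts, 7 were higher in pup 1 with a median of -0.62 at percentile 1.82, or -0.27 with a trend on gene length and GC content removed, whereas the median TPM was higher in pup 2 (33.4 and 38.3). The globin genes Hba-a2 (10946 and 9260 TPM), Hbb-bs (9542 and 6715 TPM), Hba-a1 (4408 and 3746 TPM) and Hbb-bt (3874 and 3579 TPM) led them, and near-identical globin genes can share reads. Of the globin genes of the embryo, Hbb-bh1 stayed under TPM 1 in both pups, while Hbb-y (3.62 and 1.47 TPM) and Hba-x (1.47 and 0.58 TPM), named after their values were seen, did not.

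By list median, genes of kidney, brown fat and skeletal muscle stood below the liver genes. None of 12 kidney genes reached TPM 1 in both pups, and 8 were under 1 in both, the lowest being Umod, Nphs1 and Slc12a3. The kidney median log2 ratio was -0.88 over 9 genes at percentile 2.42, and it is the same with Kap, at 0 counts in pup 2, set to the limit of 3 counts. In that list Aqp2 had 0.92 and 3.50 TPM, Cdh16 0.67 and 3.75 TPM, Pax2 0.22 and 3.46 TPM, and Miox 0.98 and 0.70 TPM. Of 11 brown fat genes, 4 were under TPM 1 in both, the lowest Elovl3, Dio2 and Ucp1. Fabp4 had 667 and 824 TPM, Cox7a1 35.0 and 36.3 TPM, Plin1 4.26 and 15.9 TPM, and Cox8b 6.13 and 9.28 TPM, with a list median of 0.21 at percentile 84.9. The high level of Fabp4 was not shared by Adipoq (0.10 and 14.9 TPM) or Ucp1 (0.26 and 0.10 TPM) of the same list. Of 6 skeletal muscle genes, 5 were higher in pup 2 with a median of 1.78 at percentile 100. Acta1 stood at 42.3 and 163 TPM, Tnnt3 at 7.63 and 41.2 TPM, Ckm at 5.83 and 20.5 TPM and Actc1 at 8.41 and 10.3 TPM.

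Genes of stress and hormone responses stood at moderate levels. The immediate early genes Jun (64.1 and 57.1 TPM), Ier2 (37.1 and 44.6 TPM), Dusp1 (28.3 and 26.6 TPM) and Egr1 (29.4 and 23.2 TPM) led a list of 12 with 10 higher in pup 1, a median log2 ratio of -0.49 and percentile 0.36 by scaled counts, whereas the median TPM was higher in pup 2 (13.3 and 15.0). Fosb, at 0.09 and 0.08 TPM, was its only member under TPM 1 in both. Glucocorticoid response genes had a median of 0.27 at percentile 93.0 over 7 genes, among them Tsc22d3 (87.8 and 72.2 TPM), Sgk1 (26.1 and 67.5 TPM), Nr3c1 (20.0 and 23.4 TPM) and Fkbp5 (15.5 and 24.5 TPM). Hypoxia genes had a median of 0.11 at percentile 74.9 over 11 genes, among them Ldha (259 and 366 TPM), Bnip3 (147 and 321 TPM), Pgk1 (80.5 and 135 TPM) and Adm (38.1 and 26.1 TPM). Xist, the RNA of the inactive X chromosome, had 10.0 and 16.2 TPM with a log2 ratio of 0.31 at percentile 80.1. The Y-linked genes Ddx3y (5 and 0 counts), Eif2s3y (4 and 1), Uty (0 and 1) and Kdm5d (0 and 0) were near or at 0 in both pups. Both pups thus had Xist RNA with almost no Y-linked RNA, so these genes gave no sign that the pups differed in sex.

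Noncoding and mitochondrial RNA made up much of the TPM. The 7SL genes Rn7s1 and Rn7s2, near-identical copies of the signal recognition particle RNA, stood at 49106 and 49105 TPM on average and together held 13.4% of TPM (2.62% of counts) in pup 1 and 6.22% of TPM (1.00% of counts) in pup 2. Gm28437, Gm29216 and Gm28438, chromosome 1 copies of mitochondrial genes, held 2.93% and 1.55% of counts and 5.75% and 3.68% of TPM, and as copies they can share reads with the mitochondrial genes. The quantifier's interval was wide for Gm28437 (7303 to 32844 TPM in pup 1). Among the 10 nuclear genes with the highest mean TPM were also Hba-a2, Hbb-bs, Malat1 (2782 and 7091 TPM), Ppia (4796 and 4564 TPM) and the processed pseudogene Gm10123 (4446 and 3916 TPM). Mitochondrial genes held 6.36% ± 0.859 of counts (SD, n = 2) and the 100 most abundant genes 24.7% ± 2.24. In the list of abundant noncoding RNAs, Malat1, Gas5 (1014 and 615 TPM), Rn7sk (674 and 403 TPM) and Rpph1 (219 and 108 TPM) led, Terc and Rny3 were under TPM 1 in both, and the median log2 ratio was -1.04 over 7 genes at percentile 0.1, or -0.39 with a trend on gene length and GC content removed. Of 12 genes examined, 8 had over 1 annotated transcript, and for these 8 the most abundant was the same in both pups: it held 98.6% ± 0.192 of the TPM of Hsd3b1 (ENSMUST00000107016.5; SD, n = 2), 84.7% ± 0.609 of Cdkn1c (ENSMUST00000037287.6), 72.5% ± 1.96 of Dlk1 (ENSMUST00000109844.6) and 65.0% ± 3.45 of Meg3 (ENSMUST00000129245.3).

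Most genes detected in 1 pup were detected in the other. TPM 1 was reached by 14757 genes in pup 1, 15226 in pup 2 and 14266 in both, 12983 of them protein-coding, and log2(TPM + 1) correlated across 15717 genes with Pearson r = 0.961 and Spearman rho = 0.956, genes not being independent replicates. The biological coefficient of variation was 33.4% over 18670 genes. Of 13870 genes with a mean count of at least 100, 1267 (9.13%) lay over 2-fold apart, 385 higher in pup 2 and 882 higher in pup 1. Scaling by the spike-in counts gave 13644, of which 13631 were higher in pup 2.

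The genes furthest apart between the pups included several known from other organs. Higher in pup 1 were Gkn1 (248 and 0 counts, at least 87.7-fold) and Gkn2 (334 and 12 counts, 29.5-fold), which encode gastrokines of the stomach lining, Krt4 (457 and 6 counts, 80.8-fold), a keratin of the oesophagus, and Cym (4580 and 161 counts, 30.2-fold), a milk-clotting stomach protease. Higher in pup 2 were Myh1 (0 and 221 counts, at least 69.4-fold), a myosin of skeletal muscle, Adipoq (5 and 584 counts, 110-fold with a log2 interval of 5.55 to 8.41), the adiponectin gene, and Lhx1 (6 and 318 counts, a log2 ratio of 5.53), a regulator of kidney formation. The pseudogenes Gm13370 (402 and 0 counts), Gm4294 (0 and 387) and Amd-ps3 (0 and 285) also fell among the 5 furthest apart in each direction. Reads of pseudogenes can be shared with near-identical genes. The posterior mean count of Gm4294 was 1445 in pup 1 and 1469 in pup 2 and that of Gm13370 was 706 and 300, each with overlapping TPM intervals, whereas that of Amd-ps3 was 10.4 and 289 with intervals that did not overlap. Over the fixed lists, 14 of 22 medians fell outside the central 95% of random lists, 11 below and 3 above, where 1.1 would be outside by chance if genes of a list varied independently, which they do not. With the length and GC trend removed 11 did, 8 below and 3 above, and the erythroid, noncoding and kidney (-0.70) medians lay inside.

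**Figure D2:**
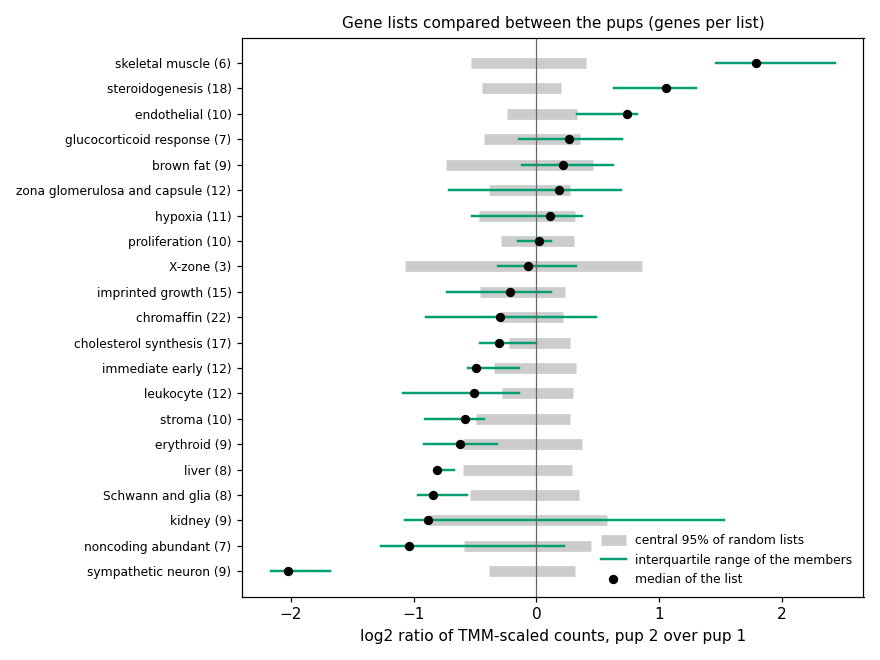
Median log2 ratio of TMM-scaled counts, pup 2 over pup 1, for each fixed list with 3 or more genes (number of genes in brackets), with the interquartile range of its members as a line and the central 95% of 10000 random lists as a grey bar. The medians run from -2.02 for sympathetic neurons to 1.78 for skeletal muscle, and scaling by the spike-in counts would shift all of them up by 2.57.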

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

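The test of library depth in this part was chosen only after the result was seen. Spike-in RNA, used only as an alternative scaling, gave 5717 reads in pup 1 and 1022 reads in pup 2, above the 3 counts that a count of 0 allows. Rows with a number as name gave 11 counts in pup 1 and 39.1 in pup 2, also above that limit.

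Spike-in reads were 5.59-fold more numerous in pup 1, or 5.50-fold as a share of each library, and 18 of the 18 spike-ins with at least 20 reads were higher there. A difference in depth is argued against, because the totals of estimated counts differed by a factor of 1.02. Another amount of spike-in per RNA may account for it, but the spike-ins did not share 1 ratio cleanly: the chi-square over its degrees of freedom was 3.02, between the bounds of 2 and 4 set beforehand, and this stays open. Taken as equal amounts, they put 13631 of 13870 genes over 2-fold higher in pup 2, and RNA content per gland was not measured. No biological explanation was tested.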

How the results depend on the processing

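The alternatives with a length and GC trend removed, with little read sharing and with TMM-scaled CPM were chosen only after the results were seen. Detected genes and the mean steroidogenic to chromaffin ratio moved by no more than their limits under every alternative run, but from summed TPM (mean 1.66) the values per pup were 1.42 and 1.90 in place of 0.50 and 2.47. Leaving out pup 1 or pup 2 gave 15226 or 14757 detected genes, and it moved no mean level, share or ratio beyond 1 SD, which the design with 2 pups fixes. No paired analysis was possible because the labels give 1 group.

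Scaling by the spike-in counts, which moves the median of all genes by 2.57 on the log2 scale, turned 13 list medians from higher in pup 1 to higher in pup 2, by construction. They were imprinted growth 2.35 and X-zone 2.50, inside the central range before, and chromaffin 2.27, Schwann and glia 1.73, sympathetic neuron 0.55, cholesterol synthesis 2.26, stroma 1.99, erythroid 1.95, leukocyte 2.06, kidney 1.69, liver 1.76, immediate early 2.08 and noncoding 1.53. It moved steroidogenesis to 3.63, endothelial to 3.30 and skeletal muscle to 4.35, and gave 13644 genes over 2-fold apart. That scaling is 1 factor for all genes.

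The count over 2-fold apart was 2949 at a mean count of at least 10 and 412 at 1000, with 18670 and 7509 genes compared. Pearson r was 0.936 with a pseudocount of 0.1 and 0.985 without a filter. The coefficient of variation was 33.4% with DESeq2 size factors and 28.5% at a mean count of at least 100. On TPM the mitochondrial share was 9.18% and that of the 100 most abundant genes 41.7%. As TMM-scaled CPM, the chromaffin level was 102 and the neuron level 163, because that unit does not divide by gene length. Among the rest, 64 list differences and 72 list levels stayed within their limits. With FPKM 7 list levels moved down, with CPM 17 moved up, with TPM over nuclear genes 7 moved up, with members of TPM 1 or more 7 moved up, and removing the length and GC trend moved 2 list differences up. FPKM and TPM over nuclear genes differ from TPM by 1 factor per library, so their moves of list levels follow from the unit. Leaving out members under TPM 1 removes low values and lowered no list level. The cause of the other moves was not tested. Depth limits genes with few counts, such as Cyp17a1.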

Other observations

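The tests of the cortex and medulla shares, of length and GC content and of Amd-ps3 were chosen only after the results were seen. The genes next furthest apart, named after their values were seen, were known from several organs and were not tested as a group. Higher in pup 1 were Tff1 (20.9 TPM in pup 1 and 0.96 TPM in pup 2), the pepsinogen gene Pga5 (32.5 and 1.67 TPM), the keratin gene Krt13 (3.87 and 0.26 TPM), Xlr4b (6.04 and 0.47 TPM), Myh6, a myosin of heart muscle (0.90 and 0.11 TPM), Sprr2a2 (21.3 and 1.93 TPM) and Bpifb1 (12.8 and 1.18 TPM). Higher in pup 2 were Uncx (0.21 and 9.59 TPM), Atp1b4 (0.13 and 2.48 TPM), Pax8, a transcription factor of kidney and thyroid (0.43 and 7.45 TPM), Car3 (4.01 and 65.9 TPM) and the titin gene Ttn (1.22 and 13.3 TPM), besides Myh3 (0.21 and 4.80 TPM) and Pax2 of the fixed muscle and kidney lists.

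For the organ genes seen mainly in 1 pup, reads shared between near-identical genes are argued against for the 12 furthest apart in each direction other than pseudogenes, whose posterior SD was a median of 0% of the count, but go with the 3 pseudogenes at a median of 62.3%, although Amd-ps3, at 13.0% just over the bound of 10% set beforehand, had TPM intervals 2.91 apart on the log2 scale, so that sharing does not account for its whole difference. Traces of neighbouring tissue may be in the libraries: genes written down before their values were looked at had median log2 ratios of -1.69 for stomach and oesophagus (11 of 12 higher in pup 1), 1.37 for nephron formation (7 of 10 higher in pup 2) and 1.68 for skeletal muscle (10 of 10 higher in pup 2). Further adipocyte genes had 0.99 (9 of 9 higher in pup 2), just under the bound of 1, and stay open. The lists share no gene with the fixed lists, but both libraries had 3 of 18 stomach, 6 of 10 nephron, 3 of 10 adipocyte and 7 of 11 muscle genes at TPM 1, and of their most abundant members Pnpla2 (log2 ratio 0.90) and Myl1 (0.76) went with their lists, Krt14 (-0.12) barely did and Eya1 (-0.81), like the median of the fixed kidney list, went against its list. No further list was written for liver. Its 8 fixed genes stood at a median of 451 TPM in pup 1 and 333 TPM in pup 2, and all were higher in pup 1. Traces of liver tissue, dissection, carry-over between libraries and differences between the pups themselves were not tested.

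For the neuron genes higher in pup 1 and the steroid genes higher in pup 2, a lower share of cortex in pup 1 was examined. The version that raises all other types alike is argued against. The endothelial and neuron medians lay 2.75 apart on the log2 scale, beyond the 0.48 of their combined half-ranges. A lower share of cortex that raises other types unequally was not tested and stays open. The Schwann and glia (-0.84), stroma (-0.58) and leukocyte (-0.50) medians had the sign of the neuron median, and the endothelial median (0.73) the opposite sign. More medulla in pup 1, raising chromaffin and neuron genes alike, is argued against too, since the chromaffin median (-0.30, lowest member -1.32) lay 1.72 above the neuron median, beyond 0.93, and Chga, Chgb, Th and Npy were higher in pup 2. Length and GC content are argued against as the whole cause, since the steroid and neuron medians stayed 3.05 apart after their trend was removed, from 3.07. More neurons in the pup 1 library may contribute: 13 further neuron genes, all higher in pup 1, had a median of -1.72, among them Uchl1 at 466 and 255 TPM, Rtn1 at 310 and 105 TPM and Stmn3 at 188 and 68.5 TPM. All 13 were also at TPM 1 or more in pup 2, so the gland may express them too, and a difference between the pups in innervation stays open as untested. The pup 1 library also had higher stomach and oesophagus genes (median -1.69). Whether the neuron RNA came from the gland or from neighbouring tissue was not tested.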
